A study of Mus musculus with 6 samples.

How the data were processed

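RNA was measured in CD4+CD8+ double-positive thymocytes sorted from mice of 8 weeks, 3 animals with a floxed Kansl1 gene and no Cre (control) and 3 with the same floxed gene and Cre driven by the Cd4 gene (KANSL1-deficient). Groups and replicate numbers were taken from the sample labels, and no library was left out. The submitters state that the controls were littermates. Only the KANSL1-deficient mice carry Cre, so an effect of Cre itself cannot be told apart from one of Kansl1 loss. The labels do not say that equal replicate numbers mark a shared litter or day, so the libraries were compared as 2 unpaired groups.

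Per the submitters' processing notes, STAR, featureCounts and DESeq2 were used with the GRCm39 build; their versions are not given in the sources used here. The deposited table of read counts lists 29626 genes with whole-number counts per library. The authors deposited a second table of FPKM values for the same genes. The gene lengths implied by the counts and the FPKM values were the same in all 6 libraries. Per the file headers, the authors' comparison gives a mean normalized signal per gene, a fold change as a ratio, a log2 fold change and a p-value with its adjusted p-value, for KANSL1-deficient over control. The library kit selects polyadenylated RNA, per the labels' protocols, and whether reads were counted by strand is not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as the replication-dependent histone genes and the interferon-induced gene families, can therefore be shared between genes, and histone transcripts mostly lack a poly(A) tail. The counts are sums over whole genes, so an exon deleted by Cre cannot be separated from the rest of Kansl1.

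The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling, the default filter on low counts by group (minimum count 10, minimum total 15), robust dispersion shrinkage and Benjamini-Hochberg adjustment at 0.05. CPM values below are scaled by the TMM factors. The standard error of a log2 fold change was its size divided by the square root of the test's F value. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment over the lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. The use of T cell receptor alpha (Tra) segments was compared as the log2 ratio of summed CPM of joining segments Traj40 and above over Traj20 and below, with an exact two-sided permutation test over the 20 assignments of the libraries, whose smallest p is 0.1. The same was done for listed 5' and 3' variable (Trav) segments.

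The tests, 39 gene lists, 12 lists of cell type markers and the rule for named genes were fixed before the data were examined. Named genes were Kansl1, a panel of 14 genes, the 10 genes per direction with the largest fold change among protein-coding genes past the threshold with at least 5 CPM on average and no overlap between the groups, and up to 4 members with the smallest p of each list with a member past the threshold. Some genes that this rule names are not reported here. Receptor segment genes and genes with provisional names were left out of the ranking by size. Alternatives were median-of-ratios scaling, library totals, no filter, a filter of at least 5 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, limma on log2 of FPKM plus 1 or plus 0.1, quantile-normalized FPKM, replicate number as a block, and each library left out in turn. Removal of each library's trend on transcript GC content, gene length or abundance (lowess, span 0.3) was added after the data had been seen. GC content came from the longest transcript of each gene in the GENCODE M21 annotation, matched by gene identifier, and was found for 97.2% of the tested genes. Coordinates are those of the deposited table in GRCm39.

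Library totals lay between 19361968 and 22459830 counts. Counts were simulated from these libraries' means, depths and dispersions for 15353 genes. The changed genes were drawn only from those with a mean of at least 5 CPM, so recovery among less abundant genes was not measured. The test recovered 8 of 67 genes changed 1.5-fold (11.9%), 50 of 67 changed 2-fold (74.6%) and 66 of 66 changed 4-fold. It called 9 of 15153 unchanged genes. In a step on 14790 genes, the mitosis list shifted by 1 on the log2 scale was called by camera, and 0 of 45 other lists were called. Simulated genes vary independently, so this gives no error rate for lists of genes that vary together.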

Results

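Transcripts were counted in double-positive thymocytes, the CD4+CD8+ stage at which the T cell receptor alpha gene is rearranged, from 3 control mice with a floxed Kansl1 gene and 3 mice that also carry Cre driven by the Cd4 gene, labelled as KANSL1-deficient. KANSL1 is a subunit of the NSL complex, which contains the histone acetyltransferase KAT8. The comparison addressed which transcripts differ between these genotypes at this stage. The libraries held 19361968, 21975201 and 21576009 counts in control replicates 1 to 3 and 21850642, 22459830 and 20603137 in KANSL1-deficient replicates 1 to 3. The labels number the mice of each group, and every pair of libraries differed by more than counting noise, so no library was a copy of another.

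The targeted gene was examined first. Kansl1 (ENSMUSG00000018412, GRCm39 chromosome 11, 104224055 to 104359687) was read at 214, 189 and 230 CPM in the control libraries and at 146, 168 and 188 CPM in the KANSL1-deficient libraries. The means were 211 ± 20.8 and 167 ± 21.3 CPM (SD, n = 3 each). The log2 fold change was -0.33 ± 0.14 (SE), which did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.171). An exact two-sided permutation test of the CPM gave p = 0.1, the smallest value 3 against 3 libraries allow. These whole-gene counts include reads outside any deleted exon, so they check the labels only weakly. Kat8, which encodes the acetyltransferase, was read at 14.2 ± 3.35 and 14.3 ± 3.07 CPM (SD, n = 3 each). Of 11 tested members of the KAT8 complexes without Kansl1, 0 passed the threshold with edgeR, DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05 with edgeR.

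Mitosis genes had the largest median change of the 38 gene lists tested: 32 of 35 tested genes of the G2/M list rose in the KANSL1-deficient cells, and the median log2 fold change of the list was 1.75. Nek2, a centrosomal kinase (ENSMUSG00000026622, chromosome 1, 191553556 to 191565162), went from 4.17 ± 2.05 to 30.5 ± 3.50 CPM (SD, n = 3 each). Nusap1, which binds spindle microtubules, went from 18.6 ± 8.72 to 103 ± 9.04 CPM, and Kif2c, a kinesin of the centromere, from 3.64 ± 0.957 to 18.8 ± 2.27 CPM. Cenpa, the centromeric histone H3 variant, had the smallest p of the list, with a log2 fold change of 1.27 ± 0.13 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00255). Of 42 tested G1/S and DNA replication genes, 20 rose and none fell, with a median log2 fold change of 0.70. They included the replication licensing gene Cdc6 (1.53), the cyclin gene Ccne2 (1.48), E2f2 (1.02) and the ribonucleotide reductase gene Rrm2 (1.55). Of 28 tested replication-dependent histone genes, 9 rose, among them H2bc8 and H2ac6, with a median of 0.89. Adjusted over the list alone, 34 mitosis genes, 32 G1/S genes and 16 histone genes were higher, and 1 G1/S gene was lower. Camera with the preset correlation called these lists at adjusted p = 8.34e-26, 2.97e-13 and 1.10e-12. With an estimated correlation none passed (adjusted p = 0.149 for each of them). The mitosis count was 18 without control replicate 2, and the G1/S count was 12 without KANSL1-deficient replicate 2. The histone count was between 2 and 5 with any 1 library left out. Markers of double-negative thymocytes, the stage before, had a median log2 fold change of 0.44 in the same libraries.

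**Figure D1:**
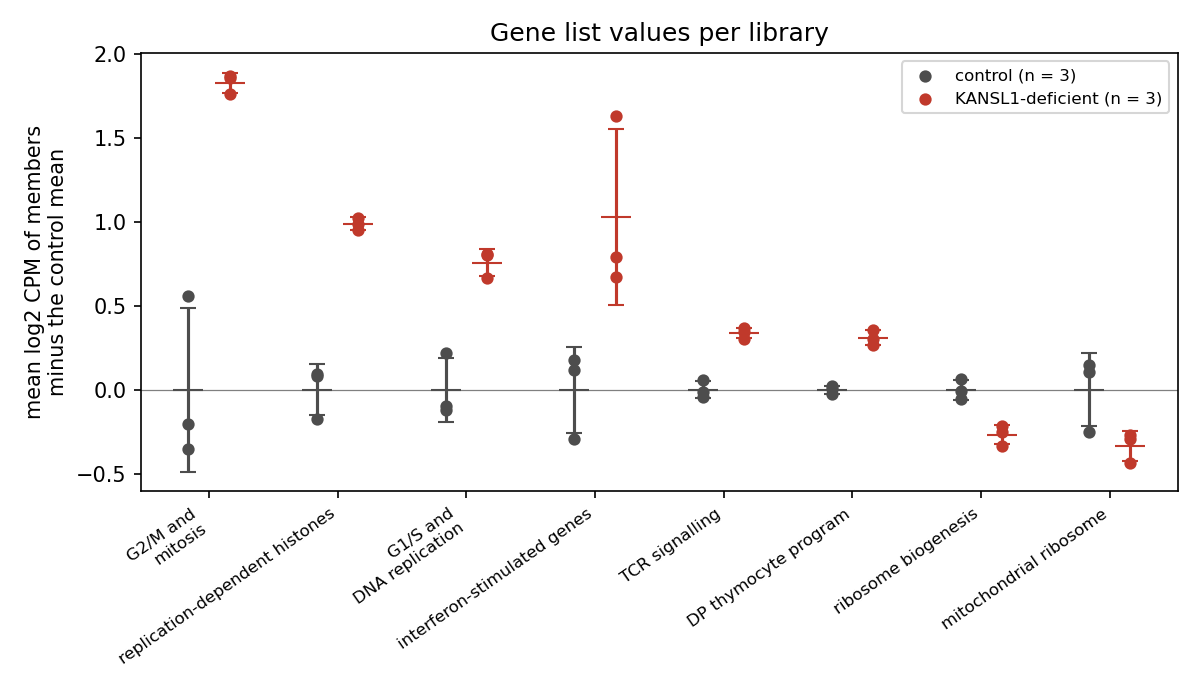
Mean log2 CPM of the tested members of 8 gene lists in each library, relative to the control mean; points are libraries, and bars show the mean and SD of 3 libraries per group. The 3 KANSL1-deficient libraries lay between 1.76 and 1.87 for mitosis genes, against -0.35 to 0.56 in the controls, and KANSL1-deficient replicate 1 stood highest for interferon-stimulated genes at 1.63.

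Over all genes, 1038 of 15353 tested genes passed the threshold, 591 higher and 447 lower in KANSL1-deficient cells, and 448 of them differed at least 2-fold, 230 higher and 218 lower (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 1038 genes, 1036 did not overlap between the groups, as did 28.5% of all tested genes, where chance gives 10%. Among changed protein-coding genes with at least 5 CPM on average and no overlap between the groups, those with the largest rise included, besides cell cycle genes, Ifit1, an interferon-induced RNA-binding protein (log2 fold change 2.66 ± 0.41, SE), Pcsk1, a prohormone convertase (2.65 ± 0.38), and Dglucy (2.34 ± 0.42). Those with the largest fall under the same limits were Ssh1, a cofilin phosphatase (-2.27 ± 0.57), Trim62 (-2.26 ± 0.35), Slc38a7, a lysosomal glutamine transporter (-2.25 ± 0.28), and Fastkd2, a mitochondrial RNA-binding protein (-2.09 ± 0.30). Urb1, a ribosome biogenesis factor, fell by 1.81 on the log2 scale. The share of changed genes that were higher was 56.9% with TMM scaling and 27.7% with library totals (30.5% with log2 FPKM), a choice that moved all genes by 0.15 on the log2 scale, so directions are relative to the TMM scale. The number of changed genes was 339 without control replicate 2, and 283, 305 and 525 without KANSL1-deficient replicates 1, 2 and 3. The authors' deposited table lists 2018 genes with an adjusted p under 0.05 and marks those that also changed at least 2-fold, 640 genes, 292 higher and 348 lower. Of these 640, 422 passed the threshold here, all in the same direction.

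Fold changes varied with abundance. When the tested genes were ranked by mean CPM into 10 groups of equal size, 203 of the 1536 most abundant genes were higher and 4 lower, and their median log2 fold change was 0.20. In group 5, 53 genes were higher and 65 lower, with a median of -0.13.

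**Figure D2:**
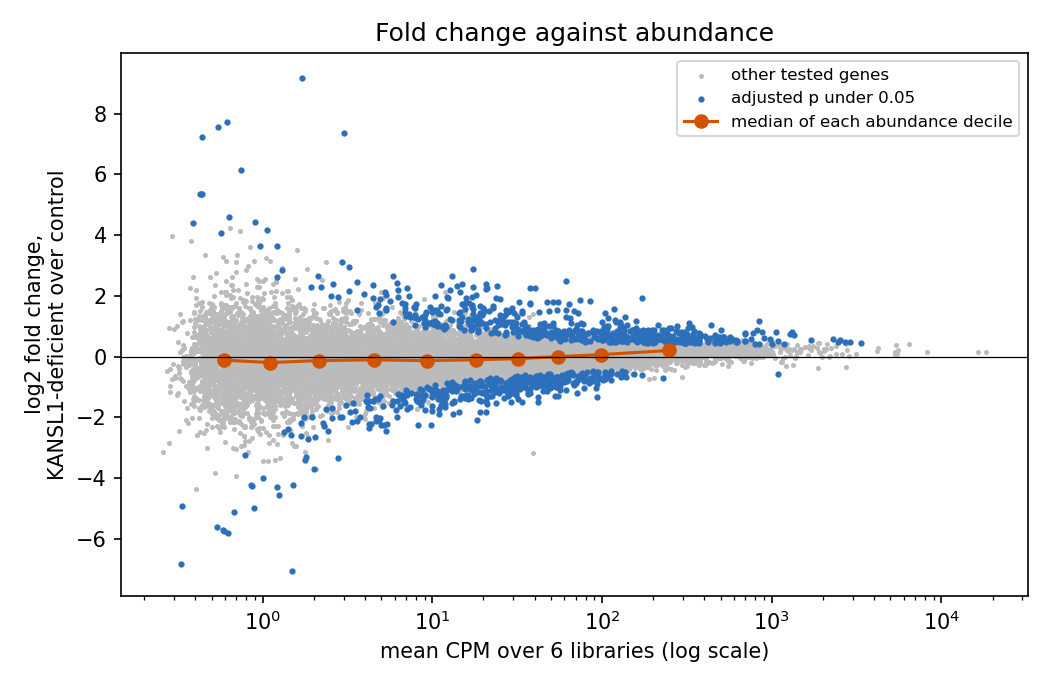
Log2 fold change (KANSL1-deficient over control) of each tested gene against its mean CPM over the 6 libraries on a log axis; blue points passed an adjusted p of 0.05, and orange points join the medians of 10 groups of genes of rising abundance. The medians go from -0.12 in the least abundant group to 0.20 in the most abundant.

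Some genes of the double-positive program and of T cell receptor signalling rose and none fell. In the double-positive program, 6 of 27 genes rose, with a median log2 fold change of 0.27. They included the recombinase gene Rag2 (72.5 ± 8.68 to 145 ± 28.2 CPM; SD, n = 3 each) and Dntt, which encodes terminal transferase (log2 fold change 0.48). Rag1 had a log2 fold change of 0.08, Cd4 of 0.27, Cd8a of 0.35 and Cd8b1 of 0.08, and none of them passed the threshold. With library totals, those of Rag1 and Cd8b1 were -0.07 and -0.07. Of 35 T cell receptor signalling genes, 11 rose, among them Tespa1 (0.85), Sla (0.80), Prkcq (0.58) and Lcp2 (0.56), with a median of 0.31. Adjusted over the list alone, 12 and 16 genes of these lists were higher. Camera called both (adjusted p = 3.41e-05 and 2.41e-06), and neither passed with an estimated correlation (adjusted p = 0.149 for both). After removal of the trend with abundance, chosen after seeing the data, camera called neither, and the medians were -2.13e-04 and 0.18. With any 1 library left out, 1 to 5 and 1 to 9 genes rose.

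Lists of positive selection, single-positive maturation and p53 targets also had more higher than lower members. In the positive selection list, 5 of 25 genes rose, among them Gata3, Itm2a and Id3 (log2 fold changes 0.87, 0.89 and 0.88). Cd5 rose from 204 ± 26.4 to 301 ± 45.8 CPM (SD, n = 3 each), while Cd69 had a log2 fold change of 0.53 that did not pass with edgeR and did with DESeq2. In the maturation list, 5 of 23 rose, including Slfn2 (0.74) and Ifngr1, an interferon-gamma receptor gene (0.54). In the p53 list, 6 of 31 rose, including Sesn1 (0.88), Ccng1 (0.87), Fas (0.59) and Ckap2 (1.42), a spindle gene. Cdkn1a and Trp53 had log2 fold changes of 0.45 and 0.42 and did not pass with edgeR, while DESeq2 called Trp53 higher. Adjusted over the list alone, 14, 9 and 11 genes were higher in the 3 lists, and 0, 1 and 1 lower. Camera called the 3 lists (adjusted p = 0.00141, 0.00592 and 0.00315), and none passed with an estimated correlation (adjusted p = 0.408, 0.229 and 0.292). With any 1 library left out, 1 to 5, 2 to 4 and 3 to 5 genes rose, and after removal of the abundance trend the positive selection list was not called (median 0.18). The mean log2 CPM of the positive selection list in KANSL1-deficient replicate 3, relative to the control mean, was 0.08, below control replicate 3 at 0.13. For p53 targets it was 0.06 in that library, against 0.35 and 0.38 in the other KANSL1-deficient libraries and 0.04 in control replicate 2. Markers of CD4 single-positive and regulatory T cells had median log2 fold changes of 0.47 and 0.51 in the same libraries. In each list 4 of 6 tested members were positive, and Gata3 is in both the positive selection and the CD4 list. The 4 tested CD8 single-positive markers had a median of -1.48. The CD4 marker Zbtb7b was read 0 times in control and 1 time in KANSL1-deficient libraries, and the regulatory T cell marker Foxp3 3 and 1 times. Myc rose (log2 fold change 0.87), whereas Bcl2l1 (0.44) and Bcl2 (0.11) did not pass with edgeR; DESeq2 and limma-voom called Bcl2l1 higher. With library totals the log2 fold change of Bcl2 was -0.04.

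Of 36 tested interferon-stimulated genes, 9 rose, and the median log2 fold change was 0.84. Ifi47, an interferon-induced GTPase, went from 72.0 ± 8.75 to 167 ± 26.5 CPM (SD, n = 3 each). Iigp1 was read 2 times in the control libraries together and 366 times in the KANSL1-deficient libraries, a ratio of 197 with a 95% Poisson interval of 54.1 to 1631 that covers counting error only. KANSL1-deficient replicate 1 was the highest library of its group, and without it 3 genes passed and the median was 0.45. With another library left out 3 to 6 genes passed. Relative to the control mean, KANSL1-deficient replicate 1 also had the highest mean log2 CPM of its group for some other lists. It was 0.47 for macrophage markers (-0.18 and -0.10 in replicates 2 and 3) and 0.43 for immediate early genes (-0.15 and -0.23). It was 0.33 for gamma-delta T, NK and NKT markers (-0.76 and -0.69). For erythroid markers it was the lowest of its group (-0.67). In the list of MHC class I presentation, 4 of 19 genes rose, including Tap1 (0.62), H2-K1 (0.86) and Psmb9 (0.64). Without KANSL1-deficient replicate 1, without KANSL1-deficient replicate 2 or without control replicate 2, 0 genes of the list passed, and with another library left out 1 to 3 did; 9 had an unadjusted p under 0.05 with all libraries, and DESeq2 called 7. Adjusted over the list alone, 17 interferon genes were higher and 1 lower, and 8 presentation genes were higher. Camera called both lists (adjusted p = 9.63e-08 and 3.43e-04), and neither passed with an estimated correlation (adjusted p = 0.467 and 0.406).

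The lists of the mitochondrial ribosome and of ribosome biogenesis had negative medians (-0.35 and -0.23). Of 74 mitochondrial ribosome genes, 8 fell and none rose. Mrpl55 went from 42.6 ± 6.51 to 15.2 ± 3.85 CPM and Mrpl4 from 66.5 ± 11.9 to 32.7 ± 2.10 CPM (SD, n = 3 each). Of 42 ribosome biogenesis genes, 6 fell, including Rrp9 (-1.12), Heatr1 (-1.23) and Rrp1b (-1.11), and Wdr12 rose (0.82). Adjusted over the list alone, 15 and 12 genes of these lists were lower, and 0 and 1 higher. Camera called both (adjusted p = 5.14e-06 and 0.00766), and neither passed with an estimated correlation (adjusted p = 0.522 and 0.229). With 1 library left out, 2 to 11 mitochondrial ribosome genes and 3 to 7 biogenesis genes fell. The mean log2 CPM of the mitochondrial ribosome list, relative to the control mean, was -0.25 in control replicate 1, near KANSL1-deficient replicates 2 and 3 (-0.27 and -0.30), and 0.15 and 0.10 in control replicates 2 and 3. Control replicate 1 was also the lowest library for oxidative phosphorylation genes (-0.23) and cytosolic ribosomal proteins (-0.35).

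Of the 38 gene lists tested, camera called 13 as higher and 3 as lower with the preset correlation. With an estimated correlation it called 0, and 7 had an unadjusted p under 0.05, while fry called 8 as higher and 2 as lower. Fry called mitosis, G1/S, histones, double-positive program, T cell receptor signalling, single-positive maturation, p53 targets and chemokine receptors higher. Ribosome biogenesis and intraciliary transport were called lower. Fry did not call positive selection (adjusted p = 0.0686), interferon-stimulated genes (0.138) or MHC class I presentation (0.0525). Nor did it call the mitochondrial ribosome (0.138), chaperones (0.142) or ribosomal proteins (0.605). The other lists that camera called were chemokine receptors and trafficking (3 of 21 genes rose; adjusted p = 0.00315, and 0.149 with an estimated correlation), cytosolic chaperones (0 of 24 passed; 0.00748, and 0.467), cytosolic ribosomal proteins (0 of 79 passed; 0.0477, and 0.800) and intraciliary transport (0 of 34 passed; 0.0204, and 0.209). The median of the ribosomal protein list was 0.11 with TMM scaling, -0.04 with library totals, where it was not called, and -0.06 without control replicate 1, and the list was not called without that library or KANSL1-deficient replicate 1 or 3. Among chaperones, ribosomal proteins and intraciliary genes, 6, 4 and 7 had an unadjusted p under 0.05 with edgeR, and DESeq2 called 2 in each list. With any 1 library left out, 1 chemokine and trafficking gene rose. Adjusted over the list alone, 7 chemokine and trafficking genes were higher and 1 lower, and 0 genes of the other 3 lists passed. After removal of the abundance trend none of these 4 lists was called, with medians of 0.08 for chemokine and trafficking genes, 0.05 for chaperones, 0.03 for ribosomal proteins and -0.32 for intraciliary genes. The chaperone list was not called without control replicate 1 or KANSL1-deficient replicate 2, nor the intraciliary list without control replicate 3 or KANSL1-deficient replicate 2.

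The other 22 gene lists were not called, although single members changed. In the integrated stress response list (adjusted p = 0.103), Mthfd2 and Phgdh of folate and serine metabolism rose (log2 fold changes 1.61 and 0.81). In the DNA repair list (0.157), 5 genes rose, including Lig4 (0.74), and Xrcc5 fell by 1.00. Epc1 (0.83) and Kat7 (0.63) rose in the histone acetylation list (0.123), and Nfkbia (0.81) and Ltb (0.76) among NF-kB targets (0.118). The Notch ligand gene Jag1 fell by 4.23 and Dtx3l rose (0.74) in the notch list (0.405), whose median was 0.19 and mean -0.13. DESeq2 called 2 genes of the notch list lower, and limma-voom called 0 lower. Ndrg1 (1.09), Pdk1 (0.52) and Kdm3a (0.51) rose in the hypoxia list (0.183), and Socs3 (0.85) and Klf6 (0.48) among immediate early genes (0.462). Lss of cholesterol synthesis fell by 1.75 (0.0810), the lysosomal enzyme genes Gaa and Hexa fell by 1.41 and 0.87 and Ctsl rose (0.64; list 0.702), and mt-Nd1 fell by 0.58 among mitochondrially encoded genes (0.0810). Bmf fell by 0.59 in the pro-apoptotic list (0.591). Pdha1 rose (0.62) in the Krebs cycle list (0.829), whose median was -0.02 and mean 0.02, and Slc16a1 rose (0.77) in the glycolysis list (0.247).

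Splicing genes included Eftud2, which fell by 0.78, and Srsf2, which rose (0.73; list adjusted p = 0.526), and Med6 fell by 0.78 among RNA polymerase II and Mediator genes (0.215). The lists with 0 members past the edgeR threshold were those of the KAT8 complexes (adjusted p = 0.148; 2 members with an unadjusted p under 0.05), anti-apoptotic genes (0.558; 1), oxidative phosphorylation (0.148; 8), mitochondrial DNA maintenance (0.174; 4), translation factors (0.829; 6), the proteasome (0.829; 1) and nuclear long non-coding RNAs (0.377; 2). DESeq2 called 0, 1, 3, 1, 3, 1 and 1 of their members. The median of the translation list was 0.02 and its mean -0.02. With library totals, the medians of the KAT8, histone acetylation, anti-apoptotic, glycolysis, DNA repair, NF-kB, stress response, immediate early, splicing, translation, long non-coding RNA, B cell and thymic epithelium lists turned negative. Of the 6 sex-linked genes, 4 were tested and 0 had an unadjusted p under 0.05.

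Joining segments at the 5' end of the Tra cluster are used first. Their reads relative to 3' segments were higher in each KANSL1-deficient library than in any control library. The exact permutation test chosen for this ratio cannot bring a difference past the threshold with 3 libraries per group. The log2 ratio of 5' over 3' Traj reads was -2.58 ± 0.40 in control and -1.84 ± 0.10 in KANSL1-deficient libraries (SD, n = 3 each; exact two-sided permutation test, p = 0.1, the smallest possible). The summed 5' segments were read at 37.5 ± 17.3 and 56.0 ± 4.07 CPM, and the 3' segments at 220 ± 84.6 and 202 ± 27.9 CPM. For variable segments, the log2 ratio of 5' over 3' Trav reads was -0.38 ± 0.41 and -1.81 ± 0.32 (SD, n = 3 each; exact two-sided permutation test, p = 0.1). The Trav sums were 2.64 to 9.29 CPM, from as few as 50 counts in a library. Of 87 tested Tra segments, 0 passed the threshold with edgeR, DESeq2 or limma-voom, and 5 had an unadjusted p under 0.05 with edgeR.

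**Figure D3:**
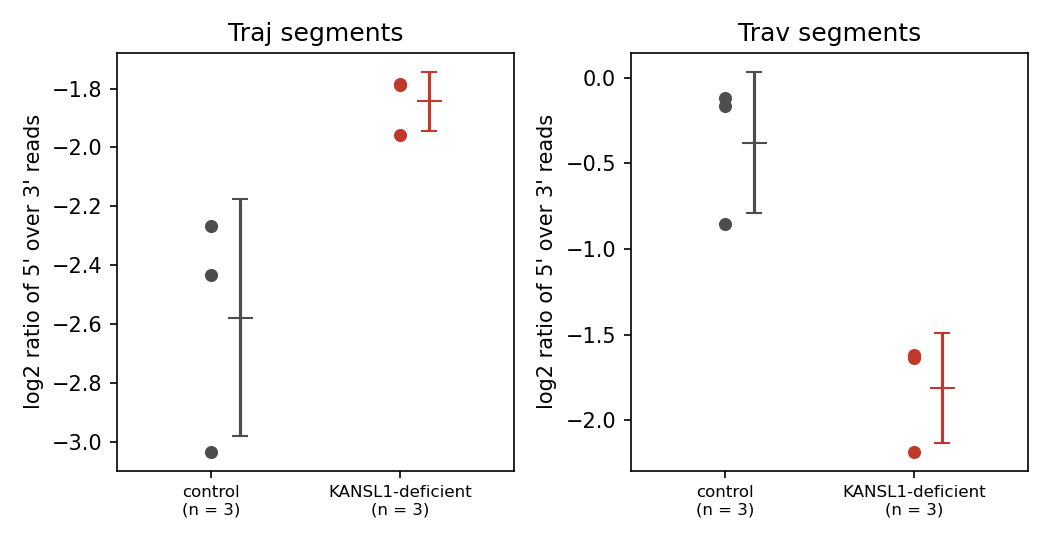
Log2 ratio of summed 5' over 3' segment reads in each library, for Traj (left) and Trav (right) segments; points are libraries, and bars show the mean and SD of 3 libraries per group. The groups did not overlap in either ratio, with means of -2.58 and -1.84 for Traj and -0.38 and -1.81 for Trav.

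Of the 9 testable lists of other cell types, 0 were called by camera or fry, and 3 had an unadjusted camera p under 0.05. Double-negative thymocyte markers had a median log2 fold change of 0.44 (adjusted p = 0.101), and 1 of 10 rose, Mycn (1.14), a growth regulator; Il2ra was read at 12.8 ± 4.44 and 17.9 ± 2.99 CPM (SD, n = 3 each). CD4 single-positive markers had a median of 0.47 and regulatory T cell markers of 0.51, each with an adjusted p of 0.101. Gata3, Icos and Cd5 rose in the first list and Ikzf2 in the second. Zbtb7b of the CD4 list and Foxp3 of the regulatory T cell list had at most 3 counts in either group. Without KANSL1-deficient replicate 3, camera called these 3 lists. The summed CD8 single-positive markers, mostly Runx3, were read at 34.0 ± 2.25 and 19.6 ± 1.37 CPM (SD, n = 3 each; exact two-sided permutation test, p = 0.1, adjusted over the 12 sums 0.171). The 4 tested CD8 markers had a median log2 fold change of -1.48, and 3 were lower adjusted over the list alone. Over all genes 0 passed with edgeR, 3 had an unadjusted p under 0.05, and DESeq2 called 3 lower and limma-voom 0. The sums of double-negative, CD4 single-positive, regulatory T, B cell, dendritic and thymic epithelium markers also did not overlap between the groups, with higher values in the KANSL1-deficient libraries (exact permutation p = 0.1 for each). Among macrophage markers Hmox1 and Axl fell by 1.30 and 2.23, and Slc40a1 was read 1 time in control and 52 times in KANSL1-deficient libraries, a ratio of 55.9 (95% Poisson interval 9.60 to 2250). The median of that list was -0.24, the direction of the test, and the mean was 0.31. B cell markers (adjusted p = 0.683) included Ighm, which rose (0.74), and the granzyme gene Gzma rose among markers of gamma-delta T, NK and NKT cells (1.14). The lists of dendritic cells (adjusted p = 0.874), gamma-delta T, NK and NKT cells (0.874), erythroid cells (0.874), thymic epithelium (0.968) and macrophages (0.968) were not called. Medians and means differed in sign for dendritic cells (0.30 and -0.05) and thymic epithelium (0.13 and -0.15). The 12 markers of endothelium and fibroblasts summed to 172 ± 34.8 and 216 ± 27.6 CPM (SD, n = 3 each), of which Pecam1 made up 167 ± 32.9 and 213 ± 27.7 CPM. The 4 tested members had a median log2 fold change of -0.52. With edgeR 0 passed and 1 was lower adjusted over the list alone, while DESeq2 called 1 lower and limma-voom 0. Neutrophil markers summed to at most 1.06 CPM in any library.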

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

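The removal of trends with GC content, length or abundance was chosen after seeing the data, and the other settings before. Kansl1 did not pass under any setting run, with log2 fold changes of -0.50 to -0.24. The Traj ratio difference was 0.51 to 0.89 with 1 library left out, 0.50 with the segments split at Traj30, 0.71 with sums of FPKM and 0.68 as a median over segments. Among the 1038 called genes, none changed sign in a setting that tested it. The stricter filter tested 958 of them, the FPKM settings 970 and DESeq2 1022. Of the 1038 genes, 1036 did not overlap between the groups, so leaving 1 library out could hardly change their sign. Of 104 called named genes, 43 stayed past the threshold in every setting that tested them.

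Library totals gave 367 higher and 959 lower genes, 413 of them lower at least 2-fold. Without a filter on low counts 1729 genes changed (845 lower), 696 at least 2-fold (387 lower), and the stricter filter gave 740 lower genes. DESeq2 called 2009 genes (1067 higher, 942 lower), of which 353 were lower at least 2-fold. Limma on log2(FPKM + 1) gave 317 higher and 722 lower genes, 296 at least 2-fold (117 higher). With a pseudocount of 0.1 it gave 284 higher genes, 127 of them at least 2-fold. Quantile-normalized FPKM gave 241 genes of at least 2-fold, 79 lower. The setting with library totals differs from the main setting only in scaling, with a median log2 fold change of -0.17 against -0.02 with TMM. Limma on log2 FPKM had medians of -0.11 (plus 1) and -0.13 (plus 0.1), and of -0.001 with quantile normalization. Stricter filtering tests fewer genes. The cause of the remaining differences was not tested.

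With 1 library left out, which also lowers n, 283 to 811 genes changed, 169 to 447 higher and 86 to 381 lower. At least 2-fold, the counts were 197 to 422, 99 to 230 and 68 to 192. Camera called 14 to 18 gene lists and 0 to 3 marker lists. It called 0 lists with an estimated correlation and 10 after removal of the abundance trend, where 7 called lists lost their call and that of mitochondrially encoded genes gained one, and fry called 10. Without a filter 1 marker list was called, that of CD4 single-positive cells. The median of the ribosomal protein list was between -0.0636 without control replicate 1, where its direction reversed, and 0.20 without control replicate 2; the cause was not tested.

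Replicate numbers gave no sign of pairing. Deviations of same-numbered libraries from their group means correlated at -0.05, -0.02 and -0.10, and no control library correlated best with its own number. With so few libraries this cannot exclude shared litters, and the submitters state littermate controls. With the replicate number as a block, 406 genes changed (242 higher, 164 lower), 267 at least 2-fold (111 lower). The Traj difference was then 0.73 (exact sign-flip permutation, p = 0.25, the smallest value this test allows). Among simulated genes with a mean of at least 5 CPM, the test found 11.9% of 1.5-fold changes and 74.6% of 2-fold changes. The effect of depth was not tested.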

Other observations

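The tests of GO terms, double-negative markers, Traj use as a stage marker, length trend, single exchanged labels and remaining Kansl1 reads were chosen after the results were seen. Among 2683 terms of the deposited gene annotation, 68 were enriched among the higher genes and 1 among the lower genes (one-sided hypergeometric test, Benjamini-Hochberg adjusted, against the 12225 tested genes with a term). Cell division held 61 higher genes of 361 (adjusted p = 1.32e-16). The cellular response to interferon-beta held 11 of 44 (adjusted p = 2.51e-04). The term passed by the lower genes was the small-subunit processome, the assembly that makes the small ribosomal subunit, with 10 of 44 where 1.46 were expected (adjusted p = 0.00362). Such tests treat genes as independent. All 6 libraries read the Y-linked gene Ddx3y at 287 to 332 CPM and Xist at no more than 3 counts.

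No other split of the 6 libraries into 3 and 3 gave a changed gene, against 1038 genes and 448 of at least 2-fold for the real split, so 1 of the 10 splits gave as many. For gene lists called by camera the real split gave 16 and the highest other split 9, so 1 of the 10 splits gave as many. For marker lists the real split and all others gave 0, so 10 of the 10 splits gave as many. The 10 splits are too few for a share under 0.05. The other splits called 4 to 9 gene lists, and each sets 2 libraries of 1 genotype and 1 of the other against the rest, so part of the genotype difference remains in them.

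Mitosis genes were higher with a median log2 fold change of 1.75. GC bias is argued against, since the median was 1.77 after removal of each library's GC trend. More double-negative cells of the stages the marker list covers were also considered. A gene read only in such cells should then rise at least as much as genes that double-positive cells also express. The 10 tested markers had a median of 0.44 (SD 0.45 over markers). Several of those markers are also read in double-positive cells and do not meet this premise, so the test cannot decide. A larger share of early cycling double-positive cells, or of cycling stages just before them that passed the sort for CD4+CD8+ cells, which should remove them, may account for the rise. The higher 5' Traj use, a log2 difference of 0.73, goes with that hypothesis and with a shorter life of the cells. That hypothesis cannot be told apart from more division per cell, because no list separates these stages. The exact permutation test chosen for the Traj ratio allows no p under 0.1. The 5' over 3' Trav ratio (-0.38 in control and -1.81 in KANSL1-deficient libraries), from as few as 50 counts in a library, was not used for this question.

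Abundant genes were higher relative to genes of middle abundance by 0.32 on the log2 scale (group 10 of the 10 abundance groups against groups 4 to 6). The difference was 0.31 after removal of the GC trend, 0.30 after removal of the length trend and 0.33 without cell cycle genes, which argues against each of these as the whole cause. The share of counts in the 10 most abundant genes overlapped between the groups (7.28% to 8.65% and 7.40% to 9.0%). So did the shares of counts in nuclear and mitochondrial rRNA genes (2.82% to 3.93% in control and 2.82% to 4.55% in KANSL1-deficient libraries), mitochondrially encoded genes (2.43% to 3.20% and 2.52% to 2.82%) and protein-coding genes (92.3% to 93.8% and 91.7% to 93.8%). A difference between the genotypes stays open, as untested, since the tables hold no values of total RNA per cell.

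Kansl1 reads in the KANSL1-deficient libraries were 79.4% of the control mean. A single library labelled as the other group, or a pair exchanged between the groups, is argued against: on the first principal component the groups were 71.9 apart, more than the widest range within a group (17.6). This test says nothing on an exchange of the whole groups. Transcript left outside the deleted exons and cells without deletion cannot be told apart, because the tables hold 1 value per gene.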
